A study of Mus musculus with 3 samples.

How the data were processed

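Single-cell RNA sequencing files of mouse duodenal immune cells from 2 saline libraries and 1 library of mice given alpha-synuclein preformed fibrils (PFF) were used, all from day 30 after injection. Per the labels, cells were freed from the duodenum with Accumax, part was sorted for CD45 and part enriched on CD11b beads, and both parts were combined. The deposited matrices hold raw UMI counts per gene and cell barcode, as whole numbers, for 32285 genes. The file headers name Cell Ranger 7.0.0, and the submitters' processing notes name the mm10 build. The annotation release, the cell calling and the way wells were joined are not given in the sources used here, nor is the number of mice per library.

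Barcodes and counts were compared between the files. Each saline file joins 4 wells, and 3 of them, with 1509, 3648 and 8732 cells, hold the same barcodes in both files with identical counts in every cell. These wells cannot serve as independent replicates, so they were counted once: they took part in clustering and are given as values of their own. The main comparison used 3 libraries, the unshared well of each saline file and PFF 1. The files as deposited, the shared wells as a further saline library and each well as a library were tried as alternatives. This design was chosen after the files were seen. The cell filter, clustering settings, class markers, 25 gene lists, tests and rule for named genes were set before the data were examined.

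Cells with at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs were kept. In the unshared wells of saline 1 and saline 2 and in PFF 1, 5459, 4332 and 12263 cells passed, with medians of 3241, 10130 and 9111 UMIs. More than 15% mitochondrial UMIs were found in 3.04%, 22.7% and 20.1% of the cells. Scrublet was run per well. Its automatic threshold marked under 0.5% of the cells in every well but shared well 2, so by the rule set in advance the highest scores were removed instead, at 0.8% per 1000 cells: 238, 150 and 1203 cells. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used in scanpy 1.11.5 (anndata 0.12.19, Python 3.11.15), without batch integration. Complement, dissociation, sex-linked, mitochondrial, ribosomal, hemoglobin, immunoglobulin and T cell receptor genes were left out of the variable genes.

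Clusters were named for the class with the most fixed markers among their 10 leading genes, with at least 3 of its markers raised and detected in at least 10% of the cells. Of the complement list only Itgax, among the cDC2 markers, was used for naming. T-like clusters were named by a rule added after the clusters were seen: Cd3d, Cd3e and Cd3g each in at least 50% of the cells, and more markers of CD8 or intraepithelial T cells than of CD4 T cells at that level. Clusters whose leading genes held more markers of another class were not named T-like. Clusters that met no rule stayed unnamed. Names end in "-like" because no protein was measured. Of the fixed symbols, 3 markers and 5 list genes were not in the files.

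UMI counts were summed per class and library and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test, 2-sided), with genes called at a Benjamini-Hochberg adjusted p under 0.05. With 1 PFF library the spread came from the saline libraries alone, with 1 residual degree of freedom, and PFF 1 was assumed to vary like them. A batch term would have left no residual degree of freedom, so batch and treatment were not separated by a fit. PFF 1 against saline 1, of the same batch per the labels, is given as a value. Log2 fold changes against single libraries used a prior count of 2. CPM in the text are raw counts relative to all UMIs of the class, and fold changes are TMM-normalised. The plan was to test classes with at least 50 cells in every library. Macrophage-like cells had fewer but were tested as planned for the question of the series, and other classes with at least 15 cells per library were added after the cells were seen. DESeq2 1.42.0, RLE normalization and no low-count filter were alternatives, as were other cell filters, doublets kept, other Leiden resolutions and each library clustered on its own. Leaving out a saline library left no residual degree of freedom and gave values only.

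For each gene list with at least 5 tested members, the median log2 fold change was placed among 10000 random lists matched on expression in 20 bins, for PFF 1 against each saline library and for saline 2 against saline 1. A list stood apart where both PFF comparisons lay below percentile 2.5 or both above 97.5. Genes were named by a rule: of the genes with PFF on the same side of both saline libraries, at 20 CPM or more and at no less than 0.25 of the level in any other class, the 12 highest and 12 lowest in macrophage-like cells and the 3 highest and 3 lowest in each other class, called genes first. A fixed set of genes, among them C1qa, C1qb, C1qc, C3, C3ar1, Itgam, Cd163, Lyve1, Mrc1 and Ccr2, was always looked up, with up to 4 members of each list spoken of. Other named genes were chosen after their values were seen.

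Shares of cells are given with exact Clopper-Pearson 95% intervals and CPM with exact Poisson 95% intervals (scipy 1.17.1). These cover counting error only. A fold against a group at 0 is a bound from 3 counts over the group. The test was tried on simulated data, 5 simulations with 200 changed genes per class. Of the 2-fold, 4-fold and 8-fold changes it recovered 38.2%, 69.3% and 83.3% in T-like cells (15254 genes), 1.79%, 19.4% and 53.9% in monocyte-like cells (6622 genes) and 0%, 0% and 2.12% in macrophage-like cells (1786 genes). Coordinates are from GENCODE M21 on GRCm38.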

Results

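Immune cells of the mouse duodenum were profiled by droplet single-cell RNA sequencing (10x 3' v3 chemistry) 30 days after saline or alpha-synuclein preformed fibrils (PFF) were injected into the duodenal wall. Preformed fibrils are aggregates assembled from the recombinant mouse protein. The mice were C57B6/J and, per the series title, male. The labels give 2 saline libraries and 1 PFF library, and place saline 1 and PFF 1 in batch 1 and saline 2 in batch 2. The saline files held 19520 and 19623 cells with 119282469 and 163433860 UMIs, and the PFF file held 15352 cells with 142955760 UMIs. Of the saline cells, 13889 were the same in both files, with identical counts cell by cell. They filled the same 3 wells and made up 71.2% of the saline 1 file and 70.8% of the saline 2 file. Only the well that each saline file did not share was used as a replicate: 5631 cells with 20788920 UMIs for saline 1 and 5734 cells with 64940311 UMIs for saline 2. Values of the shared wells are given beside them, without a test. After filtering, 5221 saline 1, 4182 saline 2 and 11060 PFF 1 cells were kept.

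The series title asks about C1q-dependent clearance of alpha-synuclein by macrophages, so the C1q genes come first. In macrophage-like cells C1qa, C1qb and C1qc, which encode the chains of the complement protein C1q, were abundant in every library, and no difference between PFF and saline passed the test. C1qa made up 5307 CPM (UMIs of the gene relative to all UMIs of the class) in PFF 1 (exact Poisson 95% interval 5041 to 5584), 5502 in saline 1 (4467 to 6705) and 4397 in saline 2 (3958 to 4873). C1qc stood at 3705 in PFF 1, 3762 in saline 1 and 3699 in saline 2. C1qb in PFF 1, at 3990, lay between 2414 in saline 1 and 5048 in saline 2. The fitted log2 fold changes of PFF over saline were 0.33 ± 1.76 for C1qa, 0.20 ± 1.75 for C1qb and 0.19 ± 1.74 for C1qc (SE, 3 libraries, adjusted p = 1.00 for each). Within batch 1, PFF 1 against saline 1 gave 0.44, 1.21 and 0.47, and against saline 2, of the other batch, the values were 0.22, -0.39 and -0.05. These fold changes are TMM-normalised, and the scaling turns the direction against saline 1 for C1qa and C1qc, whose CPM were lower in PFF 1 than in saline 1. The wells shared by the saline files had 4848, 2934 and 3180 CPM of the 3 genes in that order. In T-like cells of the same libraries C1qa lay between 0.538 and 0.965 CPM, a class that should lack the gene. The genes lie next to each other on chromosome 4 of GRCm38, minus strand: C1qb at 136880129 to 136886187, C1qc at 136889804 to 136893065 and C1qa at 136895917 to 136898803.

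**Figure D1:**
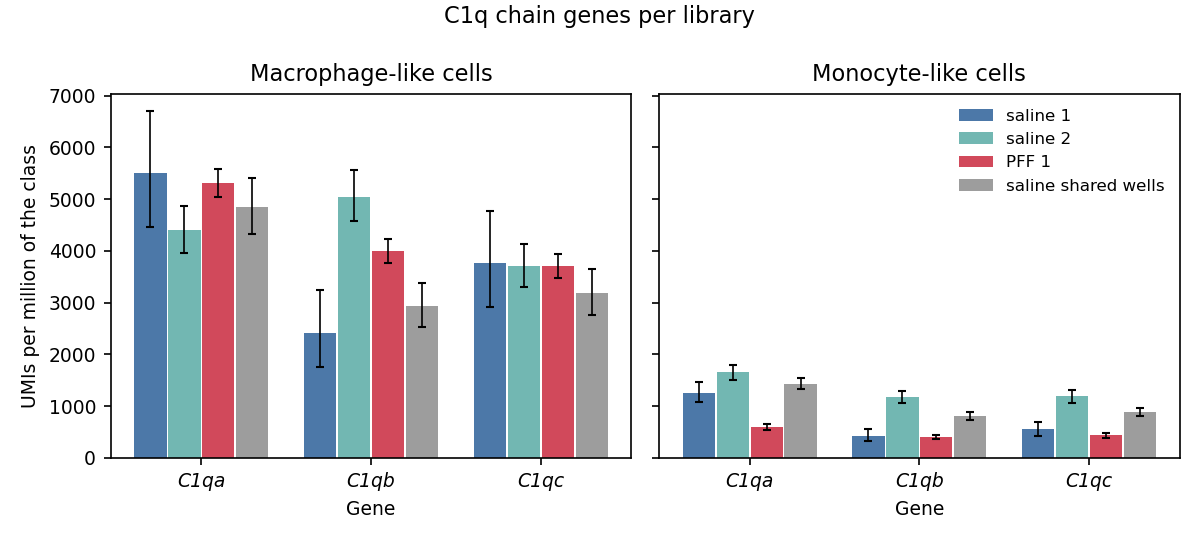
CPM of C1qa, C1qb and C1qc, relative to all UMIs of the class (vertical axis), in macrophage-like cells (left) and monocyte-like cells (right); bars are single libraries or the pooled shared saline wells, and error bars are exact Poisson 95% intervals, which cover counting error only. In macrophage-like cells the PFF 1 bar of C1qb, at 3990, lies between the saline bars at 2414 and 5048, and in monocyte-like cells the PFF 1 bar of C1qa, at 599, is below the saline bars at 1257 and 1651.

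Other complement genes of macrophage-like cells did not pass either. C3ar1, the receptor of the C3a fragment, had 110 UMIs in PFF 1, 7 in saline 1 and 16 in saline 2 (log2 0.74 ± 1.40), and C5ar1, the C5a receptor, had a log2 value of 0.54 ± 1.28. Itgam, which encodes CD11b, had 26, 0 and 13 UMIs in the same order, and Mrc1, the mannose receptor, had 54, 6 and 7. C3, Cd163, Lyve1 and Ccr2 had too few counts in this class to be tested. Over the complement list, 5 of 10 tested members had a fitted value above 0 and 5 below, with a median log2 value of 0.08.

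Across all 1786 genes tested in macrophage-like cells edgeR called 0, with 2 at an unadjusted p under 0.05, and DESeq2, over 11161 genes, called 0, with 3 at an unadjusted p under 0.05. Genes with the highest PFF values on the same side of both saline libraries, none of which passed, included the chemokines Ccl2 and Ccl4 and Cat, which encodes catalase. Ccl2 had 38 UMIs in PFF 1 and 0 in both saline libraries, at least 4.56-fold higher against a floor of 3 counts over the saline group. Ccl4 had 47 against 1 and 2 UMIs, and Cat had 36 against 1 and 3 (1.72 ± 2.40). The same ranking gave Pcnp, Cisd2, Rsrc2, Sfpq, Ddx3x, Rpn2, Tmco1, Usp34 and Capza1. At the low end it included Rbm27 (log2 -2.01 ± 1.91), Qdpr, Knop1, Dtx3l, Pbxip1, Abl1, Arl6ip5, Cebpa, a myeloid transcription factor (-1.32 ± 1.36), Glmp, Aurkaip1 and Dhx36, which did not pass either.

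Of the gene lists fixed in advance, 17 had at least 5 tested members in macrophage-like cells, and none stood apart from matched random lists in both PFF comparisons. By edgeR 0 members were called, over all genes tested or adjusted over the list alone. Phagocytic and scavenger receptors had 8 of 13 members above 0, among them the scavenger receptor Msr1 (log2 0.44 ± 1.43) and the phosphatidylserine receptor Timd4 (0.62 ± 1.30). Lysosomal genes had 14 of 23 above 0, with the protease Ctsb at 744 UMIs in PFF 1, 56 in saline 1 and 176 in saline 2 (0.26 ± 1.70) and the lipase Lipa at 0.68 ± 1.33. MHC class II genes had 5 of 7 above 0 (H2-Ab1 0.40 ± 1.79, H2-DMa 0.57 ± 1.51), MHC class I genes 7 of 10 (H2-K1 0.54 ± 1.62, B2m 0.15 ± 1.75) and interferon response genes 4 of 8 (Isg15 0.69 ± 1.31, Bst2 0.91 ± 1.34). Chemokines had 8 of 10 members above 0, at percentile 72.8 of random lists against saline 1 and 99.8 against saline 2. Nuclear genes of oxidative phosphorylation were all above 0, 21 of 21, but at percentiles 99.9 and 17.2, and the comparison of saline 2 with saline 1 gave 99.5. Members above 0 numbered 4 of 9 for tissue-resident macrophage genes, 8 of 14 for mucosal macrophage genes and 4 of 6 for alternative activation. They numbered 11 of 14 for lipid-associated genes, 3 of 6 for iron handling, 6 of 9 for oxidative stress and 3 of 5 for glycolysis. Dissociation genes had 5 of 6 above 0, at percentiles 95.3 and 99.1, and mitochondrially encoded genes 10 of 11.

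The macrophage-like class was small: 8 saline 1, 38 saline 2 and 102 PFF 1 cells with 17811, 83003 and 280174 UMIs, and in simulated data the test recovered 0% of 4-fold and 2.12% of 8-fold changes. Where macrophage-like and monocyte-like cells fell into 1 cluster, 11 genes (doublets kept) or 13 genes (Leiden resolution 0.5) were called, and with each library clustered on its own 14 genes were called higher and 61 lower.

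Monocyte-like cells, which numbered 18 in saline 1, 19 in saline 2 and 49 in PFF 1, had 18 genes called higher and 3 called lower in PFF. Retnla, an alternative activation gene of macrophages, had 1219 UMIs in PFF 1 and 0 in both saline libraries, at least 220-fold higher against a floor of 3 counts over the saline group (adjusted p 6.14e-14). Of these UMIs 1067 came from 1 cell. The shared saline wells, which the test does not use, had more Retnla than PFF 1, at 1809 CPM against 1528. Saa3, an acute-phase apolipoprotein, Marco, a scavenger receptor, and Prg4, a lubricating proteoglycan, were at least 24.2-fold, 19.9-fold and 14.8-fold higher on the same floor, and all of their UMIs came from 2 PFF cells. These 2 cells held no UMI of Ccr2 or F13a1, which are among the fixed monocyte markers. Tenm4 was at least 22.0-fold higher, with 88 of 122 UMIs in 1 cell. Cd36, a fatty acid and scavenger receptor, had 142 UMIs against 2 and 6 (log2 3.27 ± 0.73, adjusted p 0.00466), and Vcan, a proteoglycan of classical monocytes, had 70 against 0 and 1 (adjusted p 0.0181). Of the Cd36 UMIs, 49 and 44 came from the 2 cells that held Saa3, Marco and Prg4, and 78.6% of the Vcan UMIs came from 2 cells. Kcnip4, Gm12865, Lyz1, Fgfr1, Plcb1, Dapk1, Lifr and Atp8b4 were also called higher, as were Fn1, F13a1 and Ccl9, which are among the leading genes of the cluster itself. Called lower were the collagenase Mmp13 (13 UMIs against 11 and 69, log2 -3.30 ± 0.80, adjusted p 0.0150), Apoa4 and Xcl1. Apoa4, an enterocyte product, had 0 UMIs in saline 1, 102 in saline 2 and 10 in PFF 1, and so stood above saline 1. Xcl1, a T cell chemokine, had 3, 54 and 10. By the ranking for named genes Akap6 (-4.62 ± 2.71) and Bzw2 (-2.67 ± 0.77, adjusted p 0.127) followed at the low end and did not pass.

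Complement genes of monocyte-like cells did not pass the test. C1qa stood at 599 CPM in PFF 1, 1257 in saline 1 and 1651 in saline 2 (log2 -1.27 ± 0.88, adjusted p 1.00), with C1qb at -1.01 ± 0.81 and C1qc at -1.01 ± 0.82. C3, the central complement component, had 91 UMIs in PFF 1, 1 in saline 1 and 9 in saline 2 (2.37 ± 0.69, adjusted p 0.144). Itgam (0.79 ± 0.66), C3ar1 (-0.03 ± 0.66), Mrc1 (0.42 ± 0.66) and the chemokine receptor Ccr2 (0.31 ± 0.73) lay within 1 log2 unit of saline. Lyve1, a marker of resident macrophages, had 44 UMIs in PFF 1 and 0 in both saline libraries, at least 7.94-fold higher on the same floor, without passing (adjusted p 0.690). The class was below the planned 50 cells per library and was added after the cells had been seen. DESeq2 called 1 gene, and without the 2 cells that held Saa3, Marco and Prg4 edgeR called 6, all among the 21.

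Among immune cells, B-like and cycling cells made up larger shares in PFF 1 than in either saline library, and T-like cells a smaller one. B-like cells were 6.01% (519 of 8640 cells, exact 95% interval 5.51 to 6.53), against 0.721% in saline 1 and 2.87% in saline 2. Cycling cells were 2.28%, against 1.32% in both saline libraries. T-like cells were 86.2%, against 94.7% and 89.8%. With each library clustered on its own these 3 shares of PFF 1 lay within the saline range: B-like cells were 6.04% against 6.14% in saline 2, cycling cells 2.52% against 2.95% and T-like cells 87.7% against 86.0%. Of all cells kept, T-like cells were 67.4% in PFF 1 and 66.6% in saline 2, and B-like cells were 4.69% in PFF 1, 0.670% in saline 1 and 2.13% in saline 2. Germinal centre B-like cells were 0.741%, against 0.329% and 0.0967%, but 2.61% in the shared saline wells pooled. Of these 203 cells 197 lay in shared well 3, and the 3 shared wells held 0.465%, 0.369% and 3.12%. The shared wells had 3.48% B-like, 2.06% cycling and 85.7% T-like cells, so the B-like and cycling shares of PFF 1 lay above all saline values, the latter with overlapping intervals (1.98 to 2.62 in PFF 1, 1.75 to 2.40 in the shared wells). The macrophage-like share of PFF 1, 1.18%, lay between 0.165% in saline 1 and 1.23% in saline 2. Its difference from the saline mean was 0.486 percentage points, against an SD of 0.750 between the saline libraries. It lay above both saline libraries as a share of myeloid cells (35.8% against 15.4% and 24.2%, with 21.2% in the shared wells), of all cells kept (0.922% against 0.153% and 0.909%) and with at least 1000 UMIs per cell (1.09% against 0.127% and 0.937%). Monocyte-like (0.567%), cDC2-like (1.55%), pDC-like (1.17%) and plasma-like cells (0.278%) also lay within the saline range. A permutation of 3 libraries cannot give a p below 0.333, so no share was tested. Shares also depend on how the CD45-sorted and the CD11b-enriched parts of each digest were mixed. Cells left without a name were 6.22% of saline 1, 13.7% of saline 2 and 17.3% of PFF 1. Among them, cluster 12 held 1160 PFF 1, 123 saline 1 and 218 saline 2 cells and met the limit for Cd3d, Cd3e and Cd3g. So did clusters 15, 27 and 30, and the T-like share leaves out all of these.

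**Figure D2:**
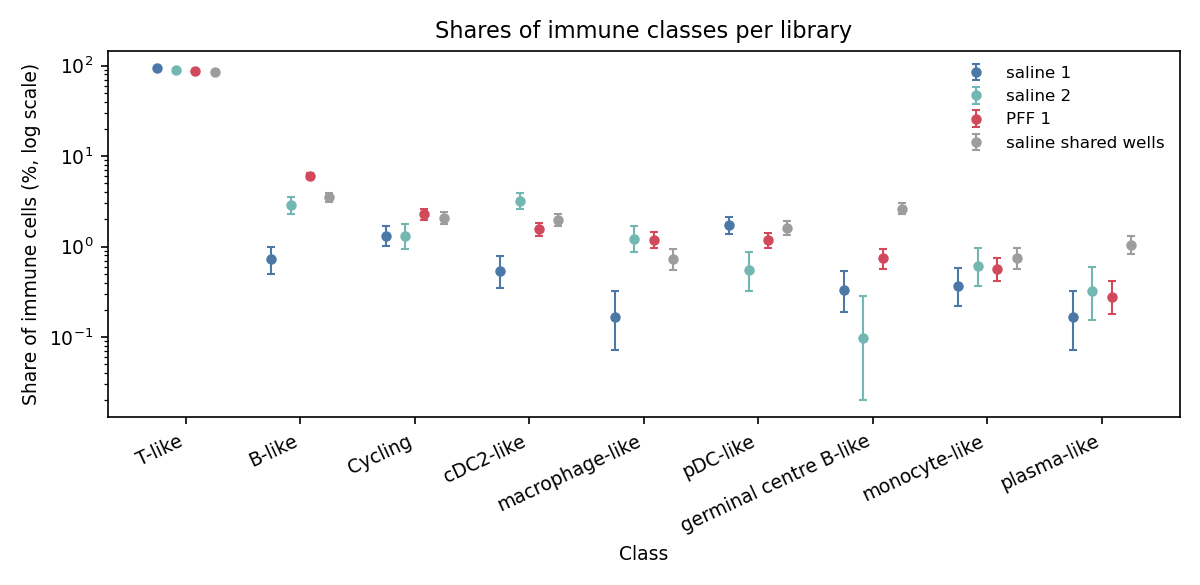
Share (%, logarithmic vertical axis) of each class among cells of the named immune classes. Points are single libraries or the pooled shared saline wells, and bars are exact binomial 95% intervals, which cover counting error only. The PFF 1 share of B-like cells, 6.01%, lies above every saline value, while the macrophage-like share, 1.18%, lies between 0.165% and 1.23%.

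In T-like cells, the most numerous class with 4598 saline 1, 2785 saline 2 and 7450 PFF 1 cells, 2 genes were called higher in PFF and 0 lower, of 15254 tested by edgeR, with 493 at an unadjusted p under 0.05. Mcpt1, a mucosal mast cell protease, had 5.85 CPM in PFF 1, 0.322 in saline 1 and 0.312 in saline 2 (log2 4.21 ± 0.53, adjusted p 0.00556). Igkc, the immunoglobulin kappa constant gene, had 29.9, 8.24 and 10.6 (1.67 ± 0.23, adjusted p 0.0103). Both are products of other cell types: Igkc reached 342110 CPM in plasma-like cells of PFF 1, and Mcpt1 was at 6.10 CPM in B-like and 10.7 in macrophage-like cells of that library. Unnamed cluster 26, whose leading genes hold the enteroendocrine genes Gip, Cck, Ghrl, Chga and Chgb beside Mcpt1 and Mcpt2, held 84 PFF 1, 5 saline 1 and 25 saline 2 cells. In T-like cells of the shared saline wells Mcpt1 was at 3.70 CPM against 5.85 in PFF 1. Igkc was at 322 CPM against 29.9, so that Igkc was higher in these saline cells than in PFF 1. Genes next in rank did not pass: Xkr6 (1.06 ± 0.21, adjusted p 0.233), Gm45894 (0.73 ± 0.21) and Gm42418 (0.68 ± 0.19) at the high end, and B930036N10Rik (-1.26 ± 0.26), Il31ra (-2.96 ± 0.71) and 9130019P16Rik (-0.85 ± 0.18) at the low end. Of 12 lists measured, nuclear oxidative phosphorylation genes stood apart, with 23 of 27 members below 0 and a median log2 value of -0.17 (percentiles 1.02 and 0 against the saline libraries), while saline 2 against saline 1 gave percentile 99.9. Against the shared saline wells the median was 0.07, at percentile 91.0, on the opposite side, and with the files as deposited no list stood apart on the lower side. The cold-inducible genes Rbm3 and Cirbp, chosen after their values were seen and not called, had 74.98 and 42.27 CPM in PFF 1, 214 and 138 in saline 1, and 145 and 69.6 in saline 2. The 2 clusters with the most T-like cells were 0 and 6 in saline 1 (1177 and 1079 of 4598 cells), 0 and 5 in saline 2 (648 and 445 of 2785) and 5 and 7 in PFF 1 (1836 and 1202 of 7450). No gene was called by edgeR with RLE normalization, with at least 1000 UMIs per cell, with at most 10% mitochondrial UMIs, with doublets kept, at Leiden resolution 0.5 or 2, or with the shared wells as a further saline library. Without the low-count filter 19 genes were called higher and 70 lower, and DESeq2 called 2 higher and 1 lower.

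Among the 3 libraries, setting a saline library apart gave more calls than setting PFF 1 apart in several classes. With saline 1 set apart from the other 2 libraries by the same test, 383 genes were called in T-like, 40 in B-like, 59 in pDC-like and 1585 in enterocyte-like cells. With saline 2 set apart, 58 genes were called in cycling cells, 29 in cDC2-like and 28 in monocyte-like cells. These counts depended on the libraries used: with the shared wells as another library, setting saline 1 apart gave 66 genes in T-like, 3 in B-like and 4 in pDC-like cells and no call by edgeR in enterocyte-like cells. Setting saline 2 apart then gave 4 genes in cDC2-like and 3 in monocyte-like cells and no call in cycling cells, and setting PFF 1 apart gave 31 in monocyte-like cells. In macrophage-like cells, where no library set apart among the 3 gave a call by edgeR, setting saline 1 apart then gave 176 genes, 50 higher and 126 lower.

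**Figure D3:**
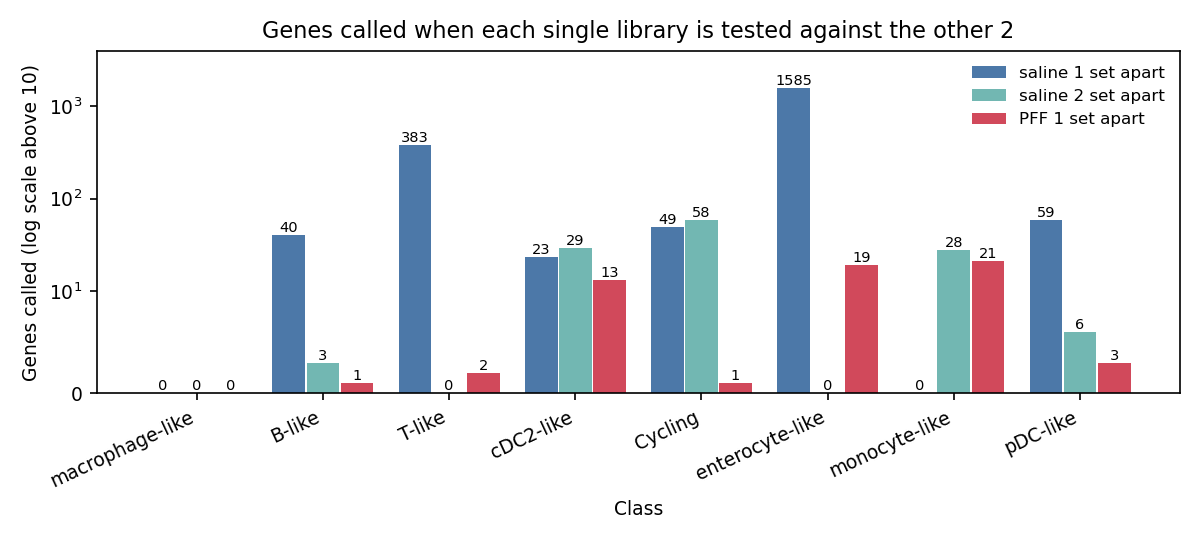
Number of genes called by edgeR (vertical axis, linear to 10 and logarithmic above) when each of the 3 libraries is tested against the other 2, per class. In T-like cells setting saline 1 apart gives 383 genes and setting PFF 1 apart gives 2; in monocyte-like cells setting saline 2 apart gives 28 and setting PFF 1 apart gives 21, an order that turned, with 3 and 31, when the shared wells were added as another library.

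Dendritic cells showed few calls. In cDC2-like cells Stfa2, a cysteine protease inhibitor, had 57 UMIs in PFF 1 against 1 and 3 (log2 3.87 ± 0.95, adjusted p 0.0421), and the lysozyme gene Lyz1 had 384 against 28 and 61 (1.80 ± 0.41, adjusted p 0.0143). Lyz1, which is among the fixed markers of secretory epithelium, was called higher in monocyte-like cells too. There its UMIs lay in 4 of 49 PFF 1 cells, with 74.4% in 2 of them. 2900052N01Rik was higher (2.18 ± 0.49), and Dlc1, Grid1 and the mitotic gene Cenpf, at 0 in both saline libraries, were at least 38.0-fold, 15.8-fold and 13.2-fold higher on the floor of 3 counts. Il4i1, an amino acid oxidase, fell in PFF 1 against both saline libraries (70 UMIs against 30 and 255 in classes of unequal size, log2 -1.80 ± 0.45, adjusted p 0.0460). Ccr7, the chemokine receptor of migrating dendritic cells, was lower (-2.02 ± 0.49, adjusted p 0.0313), with a value of -0.36 against saline 1 and -2.40 against saline 2. P3h2 and Exd1 had 0 UMIs in PFF 1, at least 23.6-fold and 21.5-fold lower against the saline libraries pooled. Olfm4, Spock1 and Gm13822 were called lower but stood above saline 1. Nek10 at the high end and Tiam2 at the low end did not pass. In pDC-like cells Cyp7b1, an oxysterol hydroxylase, had 0 UMIs in PFF 1, 3 in saline 1 and 28 in saline 2, at least 20.1-fold lower against the saline libraries pooled. The class held 573931 UMIs in saline 1 and 242630 in saline 2, so this bound rests on saline 2 and does not hold for saline 1 alone. Hivep2 and Plbd1 were called lower too, with log2 values of 1.01 and -0.86 against saline 1. Ldhb, Arpp21 and Gm14964 were highest and Rab26os and Gm39214 lowest in rank without passing. DESeq2 called 0 genes in both classes, with 31 (cDC2-like) and 14 (pDC-like) at an unadjusted p under 0.05. With the shared wells as a further saline library edgeR called 1 gene in cDC2-like and 0 in pDC-like cells. With at most 10% mitochondrial UMIs it called 0 in cDC2-like and 3 in pDC-like cells.

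B-like cells had 1 gene called, the non-coding Gm34907, with 38 UMIs in PFF 1, 0 in saline 1 and 50 in saline 2 (log2 -2.59 ± 0.55, adjusted p 0.0164). Their nuclear oxidative phosphorylation genes stood apart in the direction opposite to T-like cells, with 25 of 27 members above 0 and a median of 0.24 (percentiles 99.3 and 100). With doublets kept or each library clustered on its own no list stood apart in B-like cells. Whether the classes differ in this was not tested. Gm13822, Ei24 and Rrs1 were highest and Hcrtr2, Akr1b10 and Kcnrg lowest in rank, none passing. In cycling cells B930036N10Rik, a non-coding RNA gene, was called lower, at 42 UMIs against 26 and 87 in smaller saline classes (-2.91 ± 0.38, adjusted p 1.84e-05). Csad and Atp11a were among the highest in rank, and R3hcc1 and Abca2 followed at the low end, without passing. DESeq2 called 0 genes in B-like and 0 in cycling cells, with 14 and 27 at an unadjusted p under 0.05. B-like cells numbered 35 in saline 1, 89 in saline 2 and 519 in PFF 1, and cycling cells 64, 41 and 197. Both classes were below the planned 50 cells per library and were added later.

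Enterocyte-like cells, which the CD45 sort should exclude, numbered 38 in saline 1, 453 in saline 2 and 462 in PFF 1, and had 3 genes called higher and 16 lower. The transporter gene Slc5a12 had 6 UMIs in PFF 1, 82 in saline 1 and 202 in saline 2 (log2 -6.80 ± 0.80, adjusted p 2.96e-13), and Cubn, the receptor of vitamin B12 with its carrier, had 21, 93 and 280 (-5.26 ± 0.71, adjusted p 1.14e-09). The metallothionein gene Mt2 was lower (-3.25 ± 0.64) and so was the T cell gene Cd3e (-3.25 ± 0.62). Olfm4, a crypt stem cell gene, was higher (2.26 ± 0.50), as were the goblet cell products Tff3 (2.76 ± 0.51) and Zg16 (2.44 ± 0.51). Slfn9 and Sema5a followed in rank without passing. All 20 cell cycle genes were above 0 with a median of 1.03 (percentile 100 in both comparisons), and all 8 MHC class II genes were below 0 with a median of -0.74 (percentiles 0.350 and 0.0100). Saline 2 against saline 1 placed the cell cycle genes at percentile 100 too. The MHC class II list did not stand apart without the low-count filter, with DESeq2, with doublets kept or at Leiden resolution 2, and neither list did with at most 10% mitochondrial UMIs. The class joined cluster 8, with deep cells, and cluster 9, with a median of 1240 UMIs, and cluster 9 held 380 of the 462 cells in PFF 1, 333 of 453 in saline 2 and 23 of 38 in saline 1. With Leiden resolution 0.5, with each library clustered on its own or with at most 10% mitochondrial UMIs 0 genes were called, and DESeq2 called 2. The count was also 0 with the shared wells as a further saline library, with each well a library and without the PFF barcodes shared with saline 2.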

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

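The share given here was looked up after the clusters were seen, and no test of it was planned. Cluster 12, which no marker rule named and which the comparisons of classes therefore did not use, is led by the killer cell receptor genes Klra7, Klra6 and Klre1. It held 10.5% of the kept PFF 1 cells (1160 of 11060, exact 95% interval 9.92 to 11.1). In the unshared saline wells it held 2.36% of saline 1 and 5.21% of saline 2, and in the shared saline wells 0.711%, 0.812% and 2.42%. It drew attention as a signal in cells outside the named classes that was above the level in every control well. With 1 PFF library the difference was not tested.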

How the results depend on the processing

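The alternatives on the shared wells, on barcodes found in both PFF 1 and saline 2, on the 2 cells with Saa3, Marco and Prg4 and on classes below 50 cells were chosen after the data were seen; the others were planned. No paired analysis was possible because the groups share only number 1. Leaving out a saline library gave values and no calls. At least 1000 UMIs per cell and each library clustered on its own gave no cDC2-like or monocyte-like class, and doublets kept, Leiden resolution 0.5 and removal of the shared barcodes gave no monocyte-like class of its own. The cause of the changes below was not tested, except that the files as deposited repeat the same cells in both saline libraries, which lowers their spread.

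With the shared wells kept in both saline libraries as deposited, edgeR called 33 genes in macrophage-like, 668 in T-like, 1158 in monocyte-like, 974 in macrophage-like and monocyte-like cells together, 2100 in B-like, 782 in cDC2-like, 1381 in pDC-like, 2455 in cycling and 2328 in enterocyte-like cells, 2 lists stood apart in macrophage-like cells and 23 in other classes, and 7 other classes lay outside the saline range of shares. In macrophage-like cells, where the main count was 0, 11 genes were called with doublets kept, 13 at Leiden resolution 0.5, 75 with each library clustered on its own and 10 without the shared barcodes. In T-like cells, with 2 in the main test, the count was 0 with RLE normalization, with the shared wells as another saline library, with each well a library, with 1000 UMIs, with 10% mitochondrial UMIs, with doublets kept, at Leiden resolutions 0.5 and 2 and without the shared barcodes. It was 89 without the low-count filter and 4 with each library clustered on its own.

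In monocyte-like cells the 21 calls became 1 with DESeq2, 9 with each well a library and 6 without the Saa3, Marco and Prg4 cells. For macrophage-like and monocyte-like cells together the 10 calls became 1 with DESeq2, 32 with the shared wells as another library and 4 with each well a library. They became 16 with 10% mitochondrial UMIs and 4 without the Saa3, Marco and Prg4 cells. With 1000 UMIs 0 genes were called, and with each library clustered on its own 75. Neither of these settings had a monocyte-like class, so both counts are those of its macrophage-like class. B-like cells, with 1 call, had 0 with RLE, without the filter and with DESeq2, 6 with the shared wells as another library, 2 with each well a library, 2 with 10% mitochondrial UMIs, 8 with doublets kept and 66 clustered apart. cDC2-like cells, with 13, had 0 with DESeq2, 1 with the shared wells as another library, 2 with each well a library and 0 with 10% mitochondrial UMIs. pDC-like cells, with 3, had 0 with DESeq2, with the shared wells as another library, with 1000 UMIs and at resolution 0.5, 8 with each well a library and 16 with doublets kept. Cycling cells, with 1, had 3 with RLE, 5 without the filter, 0 with DESeq2, with the shared wells as another library, with each well a library and at resolution 2, 11 with 1000 UMIs, 6 with doublets kept, 2 at resolution 0.5, 30 clustered apart and 8 without the shared barcodes. Enterocyte-like cells, with 19, had 2 with DESeq2, 9 with 1000 UMIs, 38 with doublets kept, 43 at resolution 2, and 0 with the shared wells as another library, with each well a library, with 10% mitochondrial UMIs, at resolution 0.5, clustered apart and without the shared barcodes.

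The macrophage-like share of PFF 1 minus the saline mean, 0.486 percentage points, became -1.15 with each library clustered on its own and 15.995 of myeloid cells, where PFF 1 lay above both saline libraries, and ranged from -0.0445 to 1.02 without a saline library. Other classes outside the saline range, 4 in the main values, numbered 7 at Leiden resolution 2 and 2 with the shared wells as another library. With each library clustered on its own they numbered 3, but B-like, cycling and T-like cells were then inside the range. The median log2 fold change of the C1q genes in macrophage-like cells, 0.20, became 1.14 with each library clustered on its own. In the other planned settings it ran from -0.11 with doublets kept to 0.47 without the low-count filter, and in the summed class it was -0.02. Lists standing apart in macrophage-like cells, 0 in the main values, numbered 1 with 1000 UMIs, 1 at resolution 0.5, 5 clustered apart, 1 without the shared barcodes and 2 to 3 without a saline library. In other classes 4 of 84 became 22 to 33 without a saline library. Without a saline library a list needs to lie outside in a single comparison only. Saline 2 against saline 1 placed 3 lists outside in macrophage-like cells and 39 in other classes.

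Leaving out saline 1 or saline 2 gave log2 values from -2.86 to 3.09 for Gm34907 in B-like cells, -4.98 to 0.44 for Olfm4, -4.59 to 0.44 for Spock1 and -2.74 to 2.16 for Gm13822 in cDC2-like cells, -4.35 to 1.83 for Apoa4 in monocyte-like cells and -3.65 to 1.01 for Hivep2 in pDC-like cells; the positive values are those without saline 2 and are of the opposite sign to the main value. In enterocyte-like cells Tff3 was -2.99 and Zg16 -3.09 with each library clustered on its own, and Slc5a12 was 1.23 with 10% mitochondrial UMIs.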

Other observations

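The summed class of macrophage-like and monocyte-like cells, the tests of patterns below and the look at single clusters were chosen after the results were seen, except the drawing down of PFF cells, whose prediction was written before. The summed class held macrophage-like and monocyte-like cells in different proportions, 102 and 49 in PFF 1, 8 and 18 in saline 1 and 38 and 19 in saline 2. In it, genes of tissue-resident and muscularis macrophages stood apart as a list, with 10 of 15 tested members above 0 and a median log2 value of 0.35 (percentiles 100 and 99.0, against 68.7 for saline 2 over saline 1). Against the shared saline wells the median was -0.05, at percentile 48.5, and with doublets kept no list stood apart in this class. In the summed class 1 of its members, Marco, was called over all genes tested and 3 adjusted over the list alone. All 110 Marco UMIs of PFF 1 came from the 2 cells that also held Saa3 and Prg4. In macrophage-like cells alone the list had 4 of 9 members above 0, a median of -0.19 and no member called. In monocyte-like cells alone no list stood apart. Of 16 complement genes tested there, 2 were called adjusted over the list alone, among them C3 (log2 2.37 ± 0.69), and none over all genes.

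A cluster of 13 barcodes found in PFF 1 alone carried transcripts of several lineages at once: Cd3e of T cells at 1432, Cd79a of B cells at 383, C1qa at 318 and Apoe at 1555 CPM, with a median of 24909 UMIs. Their profiles differed by a chi-square of 1.35 per degree of freedom, against 8.13 for as many T-like cells. The 2 cells with Saa3, Marco and Prg4, named monocyte-like with their cluster, also held 25 and 11 UMIs of Timd4 and no UMI of Lyve1. They held 28 and 26 UMIs of C1qa, 11 and 3 of Icam2, and 0 and 1 of Gata6. Neither held a UMI of Ccr2 or F13a1, which are among the fixed monocyte markers. What type of cell they are was not tested.

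In 7 classes beside macrophage-like cells, the median of a list of heat shock genes was higher in PFF 1 than in each saline library in 7. The cold-inducible genes Rbm3 and Cirbp were also lower in 5 of them. In macrophage-like cells the list median was 0.98 against saline 1 and 0.69 against saline 2. Rbm3 was at -1.72 and -0.27 there, and Cirbp had no value. No heat shock gene was called by edgeR in any of these classes, and in T-like cells 10 of 17 lay above both saline libraries. Handling of the PFF library before capture may account for this, and cannot be told apart from the treatment, since there is 1 PFF library. A different mix of T-like clusters was looked at in the 9 T-like clusters with at least 50 cells per library. It was argued against for the cold-inducible part, since both genes were lower in 88.9% of these clusters. It was not for heat shock in T-like cells, since Hsph1, the 1 list gene looked at, was higher in PFF 1 in only 44.4% of them. Such a mix bears on T-like cells only. The list median was also higher in B-like (0.63 against saline 1 and 0.17 against saline 2), cDC2-like (1.12 and 0.31) and pDC-like cells (0.71 and 0.10). A response to the fibrils stays open too, but the heat shock genes were also higher in saline 2 than in saline 1 in 7 of 7 classes.

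Saline 1 stood apart from saline 2 and PFF 1, with 383 genes called in T-like cells, 216 higher and 167 lower, or 66 with the shared wells as another library, 63 higher and 3 lower. Its mix of T-like clusters was argued against as the only cause, since the shift was not confined to T-like cells. Over 6 other classes, in which 76 to 185 of these genes were tested, 83.5% of the values pooled had the same sign (72.4% to 90.4% per class). Whether the mix adds to the T-like calls was not tested within clusters. Clusters 0 and 6 held 1177 and 1079 of 4598 T-like cells in saline 1. They held 648 and 171 of 2785 in saline 2, and 211 and 438 of 7450 in PFF 1. Free RNA of T cells was argued against too, since the excess in the other classes had a median ratio of 0.922 to that in T-like cells, though it ranged from 0.472 in enterocyte-like to 1.22 in pDC-like cells. Sequencing of PFF 1 together with saline 2 stays open as a candidate explanation: the libraries shared 119 barcodes, 5.29 times the 22.5 given by the other pairs of wells, although the labels put PFF 1 in the batch of saline 1. These barcodes had a median of 59931 UMIs in saline 2 and 696 in PFF 1. Profiles correlated at a median of 0.444 within a barcode and 0.180 between different barcodes. Of the kept PFF 1 cells 99, or 0.895%, carried such a barcode. Saline 1 was not set apart again without them, so the barcodes do not show whether joint sequencing moved the T-like genes. Saline 1 also differed in depth: its T-like cells had a median of 3160 UMIs, against 9913 in saline 2 and 8850.5 in PFF 1. Before filtering, 3.04% of its cells were over the mitochondrial limit, against 22.7% in saline 2 and 20.1% in PFF 1. Whether either difference accounts for the calls was not tested. No biological explanation was tested.

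The calls in monocyte-like cells may rest on a few PFF cells, since 66.7% of the genes called higher had more than 50% of their PFF UMIs in 2 cells. If the larger number of PFF cells were the cause, the calls were predicted to fall when these were drawn down to 18. The median was 36.5 calls (5 to 119 in 50 draws), against 21 with all cells. This cannot decide the question, since the draws lay on both sides of 21. In a smaller draw against unchanged saline counts a single deep PFF cell also weighs more. The cells with Saa3, Marco and Prg4 could be 1 cell caught under 2 barcodes: their profiles differed by a chi-square of 1.15 per degree of freedom, against at least 2.91 in 91 other pairs. Their barcodes differ at 10 of 16 bases. A response of such cells to the fibrils stays open and was not tested.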
